A study of Homo sapiens with 6 samples.

How the data were processed

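Messenger RNA was measured in 6 libraries of human neurons made by forced expression of NGN2, a proneural transcription factor, in H9 and H1, which are established human embryonic stem cell lines. Per the labels, 3 libraries were WT and 3 carried a knockout (KO) of UBE3A, the ubiquitin ligase gene lost in Angelman syndrome. Batches 1 and 2 were H9 and batch 3 was H1, and each batch held 1 WT and 1 KO library. In the titles both H9 KO libraries carry the same code, both H9 WT libraries share another, and the H1 KO library has its own. If such a code marks a single KO line, batches 1 and 2 repeat that line. What else sets it apart could then not be told from loss of UBE3A. Per the labels' protocols, the neurons were grown with rat astrocytes, whole cultures were lysed in TRIzol, and libraries were made with a stranded poly(A) kit. The labels conflict in places. The description of the H1 KO library says WT while its genotype tag and title say KO, the descriptions of both batch 2 libraries say batch 1, and the day of culture is 50 in the descriptions and 40 in the protocol. Genotype and batch were taken from their own tags.

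The deposited values were raw fragment counts per gene for 58395 Ensembl genes. Per the file headers, the authors counted fragments with featureCounts 1.5.1 against Ensembl release 92 on GRCh38 (sequence of release 86), on the reverse strand, and a fragment was counted for every gene whose exons it overlapped. Trimmomatic 0.36, STAR 2.2.1 and Subread 1.5.1 are named in the submitters' processing notes. Whether rat sequence was part of the alignment index is not given in the sources used here, so fragments from rat astrocytes that aligned to human genes may be included in the counts. Genes nested in another gene on the same strand share its fragments: of 110 genes called below, 21 shared exon bases with another gene and 9 shared at least 50% of them. Gene symbols were taken from GENCODE release 29, in which 58275 of the IDs were found.

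Library totals ran from 18723294 to 30782420 fragments, so 1 fragment was worth 0.032 to 0.053 CPM, the unit of counts scaled to the library total. Across the 15 pairs of libraries, counts differed by at least 9.85 times sampling noise (chi-square over its degrees of freedom), so no pair was treated as a single library. The labels do not say that cultures were separate beyond the batch number, so p-values measure only the spread between these libraries.

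KO and WT were compared with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr, a quasi-likelihood F test with robust dispersion and Benjamini-Hochberg adjusted p under 0.05. The design fixed before the data were examined had cell line and genotype as terms, and a batch block in place of cell line was the first alternative to it. The batch tag marks a shared batch, and libraries of the same batch deviated together from their group means, with correlations across genes of 0.666, 0.536 and 0.775 against at most 0.137 for other WT and KO libraries. The group means span both cell lines, so in batch 3 this value holds the difference between H1 and H9 and cannot show pairing by batch. In the H9 batches the values go with pairing by batch number. Values with the batch block are given wherever they change a call. The tests were run on simulated counts for 19683 genes with known changes, drawn with the batch effects and the spread of the blocked fit. Batch effects shared by a pair were thus built in. The simulation therefore favours the block and cannot decide between the 2 fits. Without the block 0% of 100 genes changed 1.5-fold and 0% of 100 genes changed 2-fold were recovered, against 52% and 86% with it, where 11 of 149 calls were false. CPM in the text are TMM-scaled, means are given ± SD over 3 libraries, and log2 changes are KO minus WT ± SE. The SE is the absolute log2 change divided by the square root of the quasi-likelihood F statistic.

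Gene lists were fixed before the data were examined. Of 36 lists, 34 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation, camera tests on the residual degrees of freedom of the fit. These were 3 without the block and 2 with it, and 2 and 1 for the interaction. Few lists can pass on so few, so a call lost in this way does not by itself show that members move together. In simulated counts with 1 list raised 1.5-fold, that list was called and 0 others were. Genes were drawn independently around their batch means there, so false calls from genes that move together could not show. In the real libraries the estimated correlation reached 0.852 for the unfolded protein response and was 0.773 for cytosolic ribosomal proteins. The rule for named genes took UBE3A and KCNMA1, then per direction the 12 genes with the largest change among those called without the block, with a mean CPM of at least 1 and the same direction in 3 batches. As 0 genes were called in that fit, the places were filled, as the rule set out, with the genes of smallest unadjusted p in it. Up to 4 members per list by smallest unadjusted p and, for cell line terms, 5 genes per direction were added. Genes named outside this rule are marked as such, and some genes that the rule takes are not reported here.

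The alternatives listed at the same time were the batch block, no covariate, H9 alone, each library left out, DESeq2 size factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, an adjusted p under 0.1, and mitochondrial genes left out. Without 1 of the 2 H1 libraries, the cell line term takes up the other, and the KO difference rests on the H9 libraries. These leave-outs, H9 alone and the block without batch 3 are therefore 1 comparison and not separate checks. A correction for exon length and GC content, fitted per library by lowess, fits with the block that used DESeq2, an estimated correlation or 2 of the 3 batches, the interaction with the block and the settings of its gene lists, and leave-outs for H9, the interaction and the cell lines were added after the data were seen. In simulated counts with a length trend, the correction lowered false calls from 176 to 3.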

Results

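The data were fragment counts from 6 libraries of NGN2-induced human neurons grown with rat astrocytes, 3 labelled WT and 3 labelled UBE3A KO. The totals were 24733958, 18723294 and 27194424 fragments for the WT libraries of batches 1, 2 and 3, and 22740524, 26648937 and 30782420 for the KO libraries. The first principal component held 58.7% of the variance and set H1 apart from H9. The second, at 17.8%, set batch 1 apart from batch 2. The third, at 9.8%, was negative in all 3 WT libraries and positive in all 3 KO libraries.

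UBE3A (ENSG00000114062), a protein-coding gene on the minus strand of chromosome 15 from 25333728 to 25439056 (GRCh38), was examined first as the targeted gene. It was not lower in the libraries labelled KO. Its level was 142.6 ± 9.6 CPM in WT and 172.2 ± 2.2 CPM in KO libraries (SD, n = 3), and the KO library was the higher in 3 of 3 batches. The log2 difference of 0.27 ± 0.09 did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 1), nor did 0.27 ± 0.06 with the batch block (adjusted p = 0.0748). The UBE3A log2 fold change passed with DESeq2 and the batch block (0.28, adjusted p = 0.042) and in the H9 batches with the block (0.27, adjusted p = 0.00157, with 1 residual degree of freedom). Adjusted p over the alternatives ran from 0.00157 to 1. UBE3A counts per gene cannot show a small deletion or frameshift, so they alone do not check the genotype labels, and every direction below rests on those labels.

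KCNMA1 (ENSG00000156113), the gene of the BK calcium-activated potassium channel, was examined because the series title names a channelopathy. It lies on the minus strand of chromosome 10 from 76869601 to 77638369. It had 72.9 ± 3.5 CPM in WT and 88.1 ± 4.9 CPM in KO libraries (SD, n = 3). The log2 difference of 0.27 ± 0.07 with the batch block did not pass edgeR's quasi-likelihood test (adjusted p = 0.101), nor did 0.27 ± 0.10 without it (adjusted p = 1). Correction for exon length and GC content took the KCNMA1 value with the block to 0.15 ± 0.06 (adjusted p = 0.373). In the H9 batches with the block the KCNMA1 log2 fold change of 0.32 passed (adjusted p = 0.00188, with 1 residual degree of freedom), in a range of 0.00188 to 1 over the alternatives.

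**Figure D1:**
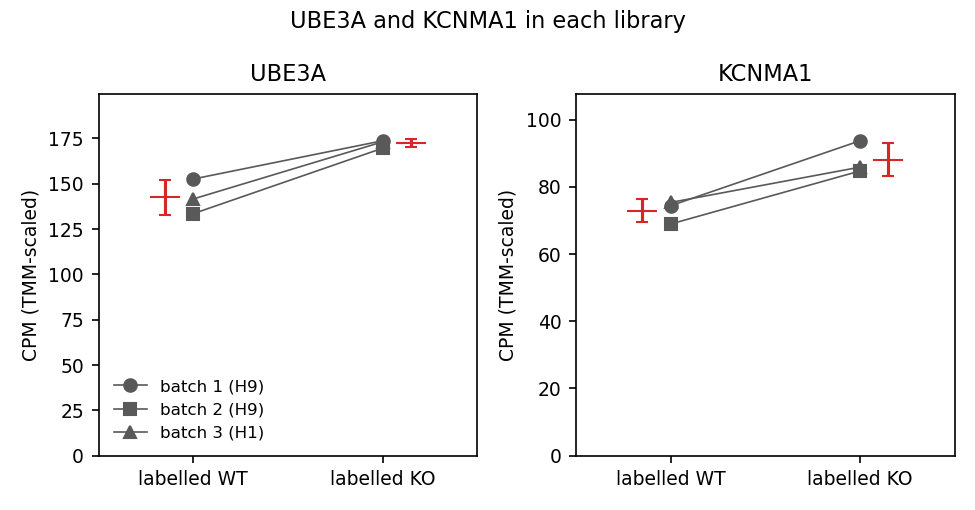
Levels of UBE3A (left) and KCNMA1 (right) in CPM in each library, with lines joining the WT and KO libraries of a batch and red bars giving the mean ± SD of 3 libraries. UBE3A was 142.6 CPM on average in WT and 172.2 CPM in KO libraries, and neither gene passed the edgeR test over all 6 libraries.

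The comparison of KO with WT asked which genes differ in neurons labelled as lacking UBE3A. With the batch block, 45 genes rose and 65 fell in the KO libraries. All 110 had the same direction in 3 of 3 batches. The blocked test picks genes whose differences within batches agree, so this is no separate support. Without the block 0 genes passed, so the genes named here rest on the pairing by batch. Among those that rose were PCDH10, a protocadherin adhesion gene, at 0.69 ± 0.08 (adjusted p = 0.00335), GRIN3A, an NMDA receptor subunit, at 0.54 ± 0.07 (adjusted p = 0.00984), and ABAT, which encodes GABA transaminase, at 0.42 ± 0.06 (adjusted p = 0.0133). INPP5F, an inositol phosphatase gene, rose from 345.7 to 496.8 CPM (log2 0.56 ± 0.07), and the pseudogene AL133461.1, which lies wholly inside its exons, rose with it and cannot be counted separately. PPARGC1A, a coactivator of mitochondrial gene expression, rose by 0.89 ± 0.16, and TRIM58, HPCAL4, INTU and CNTNAP5 rose by 1.08, 0.50, 0.56 and 0.63. After correction for exon length and GC content PPARGC1A (0.82 ± 0.16, adjusted p = 0.0521) and INTU (0.47 ± 0.10, adjusted p = 0.0661) no longer passed. CASK (0.62 ± 0.14) and PLXDC2 (0.76 ± 0.15) did not pass with the block, at adjusted p = 0.165 and 0.056.

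Among named genes that passed with the block, the largest fall was that of HEPH, the ferroxidase hephaestin, from 10.5 ± 3.7 to 2.67 ± 1.16 CPM (log2 -2.02 ± 0.21, adjusted p = 0.00168 with edgeR and the batch block). The lincRNA LINC00645 fell by 1.81 ± 0.21, TPBG by 1.23 ± 0.17, STXBP6, a SNARE-binding protein gene, by 1.20 ± 0.10, and EGLN3, an oxygen-sensing prolyl hydroxylase gene, by 1.08 ± 0.16. The transcription factor gene POU3F3 fell by 1.10 ± 0.11 (adjusted p = 0.00139). On chromosome 7, RF01978 and RF01979 also fell, but they lie wholly inside exons of HOTAIRM1 (log2 -1.10 ± 0.09; named after its values were seen) and are 1 locus with it. VIM, the intermediate filament vimentin, fell from 364.9 to 257.8 CPM (log2 -0.50 ± 0.06), and C1RL and ACKR1 fell by 1.18 ± 0.20 and 0.70 ± 0.09. The exons of C1RL overlap those of C1R, named after its values were seen, over 672 bases.

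**Figure D2:**
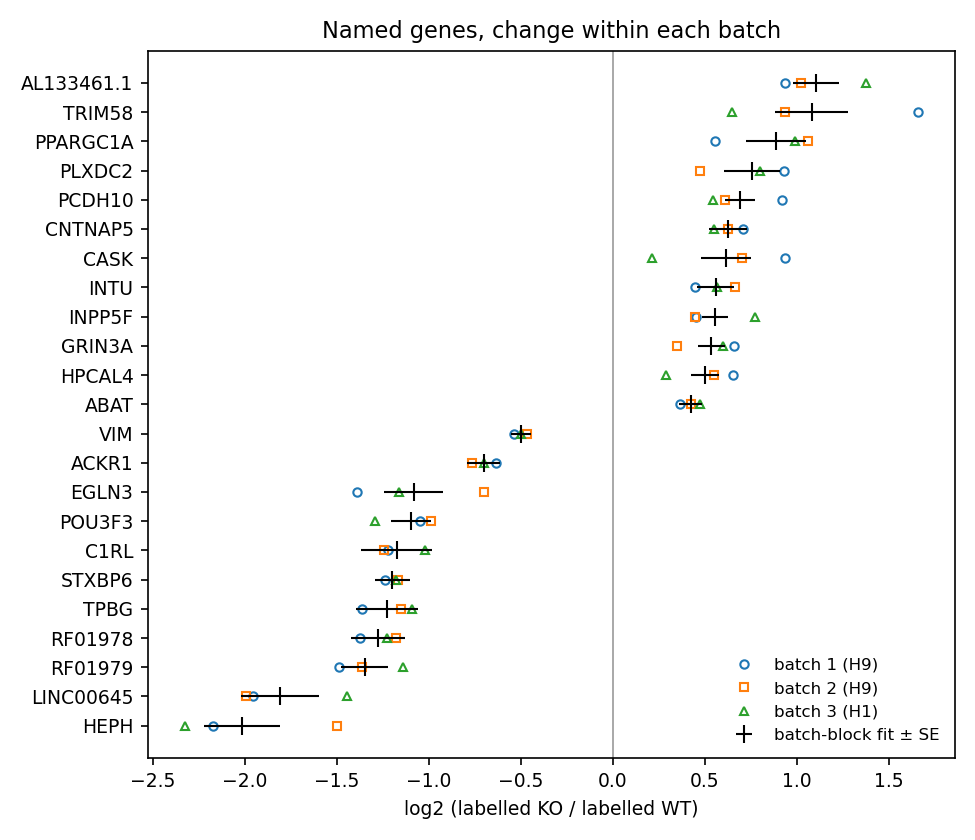
Log2 ratio of KO to WT within each batch (symbols) and the estimate with the batch block ± SE (black) for 23 genes taken by smallest unadjusted p without the block among genes with the same direction in 3 batches, which that choice therefore fixed. The estimates ran from -2.02 for HEPH to 1.10 for AL133461.1, and CASK and PLXDC2 did not pass with the block.

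Without the batch block, edgeR called 0 of 20144 genes, with 355 higher and 488 lower at an unadjusted p under 0.05, and DESeq2 called 4 higher and 22 lower. The 355 and 488 are together a smaller share of the tested genes than the 0.05 that chance alone gives. Of the 110 genes called with the block, 94 had an unadjusted p under 0.05 without it and 77 were also called after correction for exon length and GC content, 19 of the 45 that rose and 58 of the 65 that fell. Genes that rose had a median exon length of 10005 bases, against 4830 for those that fell and 3918.5 for all tested. Without batch 1 the block called 5 higher and 29 lower, and without batch 2 it called 5 higher and 26 lower.

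Among lists fixed in advance, ion channels and synapses were of first interest. Values, calls and counts of signs of members are given with the batch block, and adjusted p of lists without it unless stated. Of 66 potassium channel genes tested, 1 rose with the batch block over all genes, KCNA2 (Kv1.2) at 0.42 ± 0.07 (adjusted p = 0.0172), and 3 rose and 1 fell when adjusted over the list alone. KCNIP4 had a log2 difference of -0.77 ± 0.15 (adjusted p = 0.0521). The list was not called by camera over all 6 libraries (adjusted p = 0.138). With an estimated correlation its adjusted p was 0.901 without the block and 0.692 with it. At the preset correlation it was called higher without the H1 WT library (adjusted p = 0.0166), without the H1 KO library (0.0135) and in H9 alone (0.00722). It was also called higher with the block without batch 3 (0.00178). All of these calls take the KO difference from the same H9 libraries, so they are 1 comparison. Of 35 sodium, calcium and HCN channel genes, 27 had positive values, 0 passed over all genes and 7 were higher adjusted over the list alone. SCN8A stood at 0.31 ± 0.07, and at 0.20 after correction for exon length and GC content. Camera called this list higher (adjusted p = 0.00608), with adjusted p = 0.859 with an estimated correlation. The call was lost without the WT or the KO library of batch 1 (adjusted p = 0.15 and 0.123). Of 39 glutamatergic synapse genes, 30 had positive values, GRIN3A passed over all genes, and 12 were higher adjusted over the list alone, with DLG4 at 0.26 ± 0.06, CAMK2A at 0.36 ± 0.11 and GRIA1 at 0.30 ± 0.07 not passing over all genes. Camera gave adjusted p = 3.10e-04, and adjusted p = 0.636 with an estimated correlation. With the block, the correction took the median of the glutamatergic list from 0.13 to 0.06 (adjusted p = 5.50e-04 after it) and that of the sodium, calcium and HCN list from 0.13 to 0.06 (adjusted p = 0.013 after it). In the presynaptic list BSN (0.37 ± 0.06) and RAB3B (0.34 ± 0.06) rose, and 5 of 37 were higher adjusted over the list alone. After correction for exon length and GC content BSN and RAB3B stood at 0.257 and 0.255, and neither passed (adjusted p = 0.0612 and 0.0919).

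Other lists were called lower by camera at the preset correlation. All 76 cytosolic ribosomal protein genes had negative values with a median of -0.12 (adjusted p = 4.14e-05; adjusted p = 0.901 with an estimated correlation), and 0 passed alone, with RPS13 at -0.30 ± 0.07 and RPL17 at -0.24 ± 0.07. The ribosomal median was -0.22, -0.13 and -0.04 in batches 1, 2 and 3, and the call was lost without the KO library of batch 1 (adjusted p = 0.286) or the WT library of batch 2 (adjusted p = 0.0717). Of 18 neural progenitor genes 16 were negative (adjusted p = 1.13e-04; adjusted p = 0.389 with an estimated correlation), VIM fell, and 4 were lower adjusted over the list alone, FABP7 standing at -0.64 ± 0.15 and NES at -0.53 ± 0.17. Of 22 interferon response genes, 5 were lower adjusted over the list alone, with B2M at -0.67 ± 0.15 and HLA-B at -0.46 ± 0.12 (list adjusted p = 7.34e-04; adjusted p = 0.389 with an estimated correlation; adjusted p = 0.0504 without the H1 WT library). The p53 target list was lower (adjusted p = 0.0136; adjusted p = 0.859 with an estimated correlation), with TP53I3 at -1.85 ± 0.37 and CDKN1A at -0.66 ± 0.19, neither passing over all genes, and a median of 0.02 in batch 3 against -0.30 and -0.16 in batches 1 and 2. Its call was lost without the WT or KO library of batch 1 (adjusted p = 0.0918 and 0.332) or the WT library of batch 2 (0.0717). The cortical and forebrain list (adjusted p = 0.039; adjusted p = 0.636 with an estimated correlation) held POU3F3 and SOX5 (-0.73 ± 0.13, named after its values were seen), which fell, EOMES at -1.97 ± 0.57, and POU3F2 at 0.47 ± 0.10. Adjusted over the list alone 2 of 26 were higher and 5 lower. This call was lost without the KO library of batch 1 (adjusted p = 0.103), the WT library of batch 2 (0.0717) or the H1 KO library (0.0523). The proteasome (adjusted p = 0.039), nuclear oxidative phosphorylation (adjusted p = 0.0137) and mitochondrially encoded (adjusted p = 0.00178) lists were lower, with adjusted p = 0.903, 0.901 and 0.859 with an estimated correlation. In them PSMD14 stood at -0.23 ± 0.06 and ATP5MG at -0.23 ± 0.06. The proteasome call was lost without the WT library of batch 1 (adjusted p = 0.879), the KO library of batch 2 (0.615), the H1 WT (0.0937) or the H1 KO library (0.0938). The oxidative phosphorylation call was lost without the first 2 of these (adjusted p = 0.786 and 0.225), and its median with the block went from -0.09 to -0.05 after the length and GC correction (adjusted p = 0.0196). The mitochondrially encoded call was lost without the H1 WT or H1 KO library (adjusted p = 0.844 and 0.796). For each of these lists the H1 leave-outs and H9 alone are 1 comparison. In H9 alone the interferon, cortical and forebrain, proteasome, oxidative phosphorylation and mitochondrially encoded lists were not called (adjusted p = 0.0616, 0.0541, 0.0933, 0.0541 and 0.819), while the HOX list was called lower (8.55e-05) and potassium channels (0.00722), 15q11-q13 (0.0175), presynaptic vesicle machinery (0.0188) and cholesterol synthesis (0.0326) higher. The mitochondrially encoded list was not called with the block after correction for exon length and GC content (adjusted p = 0.0526), and all genes of the mitochondrial chromosome took 3.55% of the counts of the H1 KO library (exact 95% binomial interval 3.54 to 3.55, counting error only) against 5.28% to 5.67% of the others.

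The astrocyte list, markers of the other cell type in these cultures, was lower too (adjusted p = 0.0057; adjusted p = 0.859 with an estimated correlation). Its median was -0.02 in batch 1, -0.21 in batch 2 and -0.46 in batch 3. The call was lost without the H1 WT library (adjusted p = 0.319), without the H1 KO library (0.294) and in H9 alone (0.125), which are 1 comparison. It was also lost without the KO library of batch 2 (0.0802). VIM, also a member of the neural progenitor list, was its 1 member that passed over all genes, and 1 member was higher and 2 lower adjusted over the list alone. GFAP had 5.37 CPM in WT and 5.38 CPM in KO libraries, and SLC1A2 stood at 0.21 ± 0.06 (0.10 after correction for exon length and GC content) and PON2 at -0.64 ± 0.18. GFAP was named after its values were seen.

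In the pan-neuronal list NEFM, a neurofilament gene, fell by 0.39 ± 0.06 (adjusted p = 0.0144 with edgeR and the batch block), and GAP43 stood at -0.24 ± 0.07. In the peripheral and sensory list NTRK3, RET and PRPH rose by 0.49 ± 0.08, 0.30 ± 0.06 and 0.48 ± 0.07, while the list's median was -0.11 and camera did not call it. SLIT1 and EPHA4, of the axon guidance list, rose by 0.40 ± 0.08 and 0.43 ± 0.07, and PLXND1 stood at 1.11 ± 0.22. After correction for exon length and GC content NTRK3, RET and SLIT1 stood at 0.37, 0.26 and 0.34 and no longer passed (adjusted p = 0.0754, 0.0606 and 0.0517). In the HOX list HOXB5 stood at -1.07 ± 0.31. INPP5F was the 1 gene that passed over all genes of 21 imprinted genes outside 15q11-q13, with GNAS at -0.27 ± 0.06. Of 27 immediate early genes 20 had negative values and 0 passed, with EGR3 at -2.35 ± 0.91. In the 15q11-q13 list, 0 of 20 genes passed over all genes and 2 were higher adjusted over the list alone. SNHG14, the transcript antisense to UBE3A, stood at 0.24 ± 0.06, and at 0.11 after the same correction. Among proposed UBE3A substrates, 0 of 21 passed over all genes, with PSMD4 at -0.22 ± 0.06.

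Camera called 11 of 34 lists without the batch block and 16 with it, 0 with an estimated correlation and 0 by fry. Without the block, the estimated correlations of the neural progenitor, cortical and forebrain and interferon lists were -0.043, -0.039 and -0.006. These lie below the preset 0.01, yet these lists lost their calls too. On 3 or 2 residual degrees of freedom, the 0 calls cannot decide whether genes that move together made the others. The 5 called with the block alone were presynaptic vesicle machinery (adjusted p = 0.0131), heat shock (0.0161), hypoxia and glycolysis (0.0277), cholesterol synthesis (0.0117) and clustered protocadherins (0.0197). After correction for exon length and GC content, presynaptic vesicle machinery (adjusted p = 0.312), heat shock (0.0554) and clustered protocadherins (0.129) were not called. Left without 1 batch, each of the 5 lost its call at least once. Adjusted p was 0.258 for presynaptic vesicle machinery, 0.064 for hypoxia and glycolysis and 0.189 for clustered protocadherins without batch 1, 0.115 for presynaptic vesicle machinery and 0.704 for cholesterol synthesis without batch 2, and 0.288 for heat shock and 0.226 for hypoxia and glycolysis without batch 3. Other splits of the 6 libraries called up to 14 lists, with and without the block. The 23 lists not called without the block had adjusted p from 0.0923 to 0.964, and some of them were called with 1 library left out. Without the H1 WT or the H1 KO library, adjusted p was 0.00922 and 0.00367 for HOX genes and 0.00633 and 0.0058 for immediate early genes, both lower, and 0.023 and 0.0194 for 15q11-q13, 0.0285 and 0.0194 for presynaptic vesicle machinery and 0.0413 and 0.037 for cholesterol synthesis, all higher. Immediate early genes were not called in H9 alone (adjusted p = 0.0733) or with the block without batch 3 (0.0758), which take the KO difference from the same H9 libraries. Without the WT library of batch 1 it was 2.07e-04 for cholesterol synthesis, higher, and 0.0405 for immediate early genes, lower, and without the KO library of batch 2 it was 0.0368 for cholesterol synthesis, higher. Without the KO library of batch 1 heat shock (3.01e-04) and HOX genes (0.0398) were called lower, and without the WT library of batch 2 heat shock (0.0015) and hypoxia and glycolysis (0.0273). With the block, HOX genes were called lower without batch 1 (0.0318) and batch 3 (2.88e-07), the unfolded protein response lower without batch 2 (0.0217), and 15q11-q13 (0.00356), GABAergic and glycinergic (0.0356), axon guidance (0.0374) and imprinted genes outside 15q11-q13 (0.0289) higher without batch 3.

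**Figure D3:**
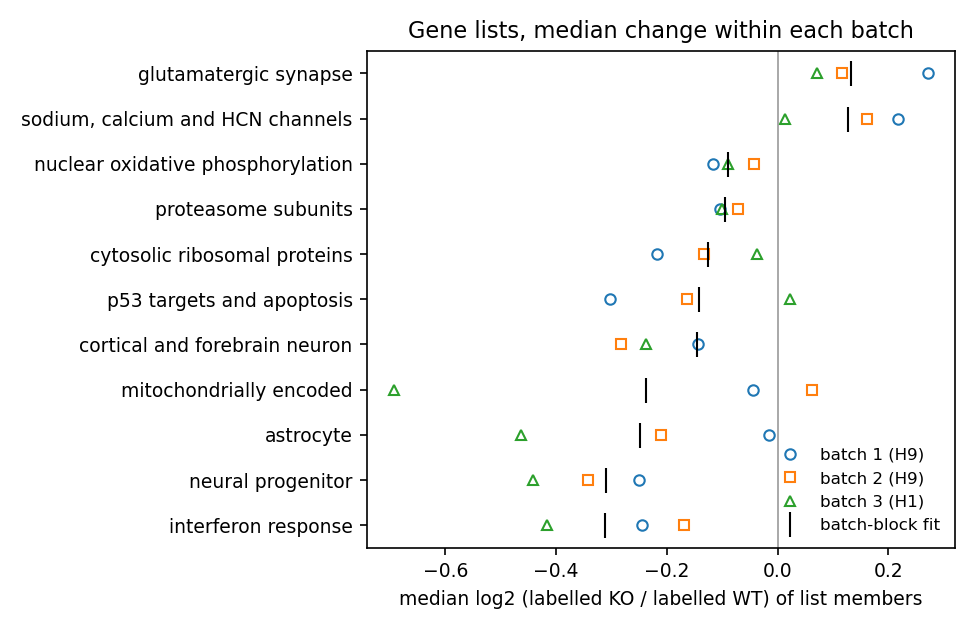
Median log2 ratio of KO to WT of the members of each of the 11 lists called at the preset correlation, within each batch (symbols) and with the batch block (black bars). The mitochondrially encoded list lay at -0.04, 0.06 and -0.69 in batches 1, 2 and 3. None of the lists was called with an estimated correlation, on 3 residual degrees of freedom.

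The agreement of the 3 batches was measured across genes, which are not independent replicates. Log2 differences of batches 1 and 2, both H9, correlated with Pearson's r = 0.178 and Spearman's rho = 0.231 over 20144 genes, and with r = 0.50 over 10949 genes with a mean CPM of at least 10. Batch 3, the H1 pair, gave r = 0.099 with batch 1 and 0.107 with batch 2. The direction was the same in all 3 batches for 7077 genes, 35.1%, where chance gives 25%.

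In H9 alone, with 2 libraries per genotype, edgeR called 0 of 19254 genes and DESeq2 called 7. In edgeR 224 were higher and 257 lower at an unadjusted p under 0.05, together fewer than chance alone gives. With the batch block 756 rose and 545 fell, with a smallest adjusted p = 2.93e-312. That fit had 1 residual degree of freedom and an infinite median of prior degrees of freedom, so that for most genes the spread was that of the fitted trend and not the gene's own.

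Whether the KO difference itself differed between H1 and H9 was tested with an interaction term. The genes of smallest p differed mostly through 1 library or 1 cell line. HERC2P2, a pseudogene of HERC2, had 3.21 CPM in the H1 WT library and 88.9 CPM in the H1 KO library, against 124.5 to 180.9 CPM in H9. PHACTR3 had 0.302 CPM in H1 WT and 47.4 CPM in H1 KO. ARMCX1 had 68.0 CPM in H1 WT and 3.24 CPM in H1 KO, and MT-CO3 had 4092 and 2114 CPM. TSPYL5 had 2.08 and 3.19 CPM in the H9 WT libraries against 0.0436 and 0.112 CPM in the H9 KO libraries. BEX5 had 1.24 and 0.372 CPM in the H9 WT libraries and 81.1 and 72.7 CPM in the H9 KO libraries. Both H9 KO libraries carry the same title code, so a trait of a KO line they share and loss of UBE3A cannot be told apart. At an unadjusted p under 0.05, edgeR without the batch block had 89 genes higher and 294 lower, together fewer than chance alone gives. Without the batch block edgeR called 0 of 21596 genes (smallest adjusted p = 0.426), and DESeq2 called 7. With it 133 genes were called higher and 425 lower, each of the 6 genes above among them, in a fit with 1 residual degree of freedom and an infinite median of prior degrees of freedom. The same fit called 0 genes with batch 1 or batch 2 set apart in place of batch 3. Those fits had a wider spread, with a common coefficient of variation of 0.115 and 0.122 against 0.075. Their median prior degrees of freedom were 13.71 and 15.71. Their residual sets an H9 pair against the H1 pair, while with batch 3 apart it sets the 2 H9 pairs against each other. The counts are thus not alike and cannot serve as a control. H1 had 1 library per genotype, both in batch 3, so cell line and batch cannot be told apart here, and HERC2P2 and HERC2P3 share near-identical sequence with HERC2, so their counts are uncertain.

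Between H1 and H9 neurons edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2411 genes, 1059 higher and 1352 lower in H1. NNAT, an imprinted gene, had 181.1 and 117.9 CPM in the H1 libraries and at most 0.16 CPM in H9. The transcription factor genes IRX1 and TLX3 were higher in H1 by 4.16 ± 0.20 and 4.15 ± 0.21 on the log2 scale, and FAR2P4 and ZNF248 by 5.39 and 5.26. TFAP2A, CALY and AC117402.1 were lower, at -4.64, -4.25 and -4.81. ZNF354C and LYNX1 were lower too, at 0.0754 and 0.164 CPM and at 0.151 and 0.197 CPM in the H1 libraries, a few fragments each, against at least 20.6 and 15.5 CPM in H9. All H1 libraries were in batch 3, so cell line and batch cannot be told apart, and the test counted the 2 libraries of a batch as independent although they deviate together, so that 1 H1 batch against 2 H9 batches entered as 2 libraries against 4 and the p-values are too small. Without the H1 WT or the H1 KO library 336 and 100 genes were called, and without the WT library of batch 1 or the KO library of batch 2 there were 1082 and 1571.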

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

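The comparison with the mitochondrial shares, the interaction with the batch block, and the estimated correlation and leave-outs for its lists were chosen after related values had been seen.

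Camera on the interaction of cell line and genotype called 10 gene lists at the preset correlation without the batch block. With an estimated correlation, on 2 residual degrees of freedom, it called 0. H1 had 1 library per genotype, both in batch 3, so a difference between the cell lines and one of that batch cannot be told apart. The mitochondrially encoded list gave adjusted p = 1.87e-11 (adjusted p = 0.696 with an estimated correlation). Adjusted p was 1.63e-05 for extracellular matrix, 0.00397 for cytosolic ribosomal proteins, 0.00631 for GABAergic and glycinergic genes and 0.00919 for the astrocyte list. It was 0.0168 for potassium channels, for sodium, calcium and HCN channels and for p53 targets, 0.021 for HOX genes and 0.0491 for the Wnt pathway. With the block, in a fit with 1 residual degree of freedom, 17 lists were called, 9 of the 10 among them but not HOX genes (adjusted p = 0.0777), and 0 with the block and an estimated correlation. With batch 1 or batch 2 set apart in place of batch 3, the blocked fit called 11 and 2 lists. The spread of these fits was wider (common coefficient of variation 0.115 and 0.122 against 0.075), so the counts are not alike. Without the block, 2 of the 10, mitochondrially encoded and extracellular matrix, were called without each of the 4 H9 libraries. Without the KO library of batch 1, adjusted p was 0.478 for ribosomal proteins, 0.207 for the astrocyte list, 0.2 for potassium channels, 0.169 for sodium, calcium and HCN channels, 0.271 for p53 targets and 0.478 for the Wnt pathway. Without the WT library of batch 2 it was 0.188 for ribosomal proteins, 0.144 for the astrocyte list, 0.177 for potassium channels, 0.0616 for p53 targets and 0.194 for the Wnt pathway. Without the WT library of batch 1 it was 0.0956 for GABAergic and glycinergic genes, 0.104 for sodium, calcium and HCN channels, 0.069 for p53 targets and 0.143 for HOX genes, and without the KO library of batch 2 it was 0.188 for HOX genes.

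In the H1 pair 4 of the genes examined lay opposite to both H9 pairs. All 4 had been taken for their small p in the interaction test, so their difference between H1 and H9 is no separate support. The opposition of signs itself was not tested. The edgeR interaction test called none of the 4 without the batch block and each of them with it, at 1 residual degree of freedom. Their log2 difference in the H1 pair was 0.68 for PRKCH, 3.28 for HERC2P3, 6.96 for PHACTR3 and -0.40 for BEX5. In batches 1 and 2 it was -1.35 and -1.51 for PRKCH and 5.94 and 7.33 for BEX5. For HERC2P3 it was -0.27 and -0.05 and for PHACTR3 -0.21 and -0.04, small changes in H9. The H1 WT library held only 0.19 CPM of HERC2P3 and 0.30 CPM of PHACTR3.

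Mitochondrially encoded genes were lower in the H1 KO library, with a median log2 difference of -0.69 in batch 3 against -0.04 and 0.06 in batches 1 and 2. A trend with gene length and GC content is argued against, since removing it took the median difference between the cell lines from -0.72 to -0.79, a ratio of 1.10 (95% bootstrap interval 1.03 to 1.21). That interval resamples genes, which share the same libraries, and does not measure the spread between libraries. All genes of the mitochondrial chromosome took 3.55% of the counts of the H1 KO library, and 5.28% to 5.67% of those of the other libraries. With 1 H1 library per genotype, that library, batch 3 and an effect of genotype in H1 cannot be told apart.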

How the results depend on the processing

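DESeq2 with the block, the length and GC correction, the block with an estimated correlation, the fits without a batch, the interaction with the block, the settings of its lists, and leave-outs for H9, the interaction and the cell lines were chosen after the data were seen. Without the block, edgeR called 0 genes for KO versus WT with no covariate, H9 only, DESeq2 size factors, the stricter filter, adjusted p under 0.1, mitochondrial genes left out and each library left out (0 to 0). The replicate block called 45 higher and 65 lower, no filter 5 and 16, DESeq2 4 and 22, DESeq2 with replicate block 104 and 120 (109 of the 110 among them), and the block with length and GC correction 21 and 69. Leaving out batch 1, 2 or 3 under the block gave 5 and 29, 5 and 26, and 756 and 545, with 28, 18 and 109 of the 110 among them and 1 residual degree of freedom each. These fits share 4 of the 6 libraries with that of the 110, so some overlap comes from shared libraries.

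In H9, no filter called 29 genes, DESeq2 7, the replicate block 1301, and leave-outs 0 to 1. For the interaction the replicate block called 558, no filter 17, DESeq2 7, and leave-outs of H9 libraries 2 to 3; without an H1 library the term could not be fitted. H1 versus H9 gave 3722 with DESeq2, 4110 at adjusted p under 0.1, and 100 to 1987 in leave-outs (1082 without WT replicate 1, 1571 without KO replicate 2, 336 without WT replicate 3, 100 without KO replicate 3). Interaction lists called were 17 with the replicate block, 0 with an estimated correlation, with or without the block, and 5 to 13 in leave-outs of H9 libraries (5 without KO replicate 1, 6 without WT replicate 2). KO versus WT lists called were 10 to 13 in leave-outs, but only 2 of the 11, glutamatergic synapse and neural progenitor, were called in all 6. Of these leave-outs, the 2 of H1 libraries take the KO difference from the same H9 libraries and are 1 comparison. The unfolded protein response list was called lower without WT replicate 1 (adjusted p = 2.46e-04) and KO replicate 2 (6.17e-05) and higher without KO replicate 1 (0.0252) and WT replicate 2 (0.0273). List calls were 0 with an estimated correlation, with fry, and with the replicate block and an estimated correlation. With a mean CPM of at least 10, r was 0.50, 0.182 and 0.195 for batches 1 and 2, 1 and 3, and 2 and 3.

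UBE3A and KCNMA1 kept their sign in every setting run. GFAP and GJA1 passed in none and changed sign. GFAP was -0.059 in H9 only, -0.084 in the block with length and GC correction, -0.063 in the block without batch 3, and -0.093 to 0.164 in leave-outs. GJA1 was -0.012 without the block, 0.087 in the replicate block, 0.113 with no covariate, 0.217 in H9 only, 0.001 with no filter, 0.088 in DESeq2 with replicate block, 0.144 in the block with length and GC correction, 0.163 and 0.322 in the block without batch 1 and 3, and -0.415 to 0.460 in leave-outs. Of the KO versus WT values of 88 genes over all settings, 1287 kept direction and side of the threshold, 265 passed it and 19 changed sign. All 19 were values of GFAP or GJA1. Most of the 88 genes were taken by smallest p in these libraries, some also by the same direction in 3 batches. Their kept signs were therefore largely fixed by that choice. Many settings without the block called 0 of these genes, so a kept side of the threshold is no support either. Of the values of 9 interaction genes 24 kept both and 21 passed, and 38 of 10 H1 versus H9 genes kept both. Apart from the counts of genes called, which it moved from 0 to 110 over all libraries, to 1301 in H9 and to 558 for the interaction, the block changed the calls of 5 KO versus WT lists, 43 of the 88 genes, the 9 interaction genes and the interaction lists. Among these lists and named genes, it changed no other call. H1 versus H9 could not be fitted with the block. Except where fewer libraries or genes were tested, the cause was not tested. Depth limits genes of a few fragments.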

Other observations

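The tests of the length and GC trend on the 110 genes and on UBE3A, their bounds, and the test of the astrocyte share with its 5 pooled genes were chosen after related values had been seen. The genes of the next paragraph were also chosen after their values were seen, and every direction rests on the KO and WT labels.

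With the batch block, the chromatin regulator gene KMT2D rose by 0.39 ± 0.06, CREBBP by 0.32 ± 0.06 and TET3 by 0.33 ± 0.06. After correction for exon length and GC content they stood at 0.267, 0.205 and 0.225. Their adjusted p were then 0.0649, 0.172 and 0.149, so none of these 3 passed. The linker histone gene H1F0 fell from 268.3 to 188.1 CPM, and the core histone genes HIST2H2BE, HIST3H2A and HIST1H2BK fell by 0.72 ± 0.10, 0.60 ± 0.09 and 1.11 ± 0.20. The G-protein regulator gene RGS4 fell by 0.64 ± 0.06, and the cyclin genes CCND1 and CCND2 by 0.88 ± 0.17 and 0.53 ± 0.08. These 7 genes that fell passed edgeR's quasi-likelihood test with the batch block before and after the correction, and did not pass without the block.

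The counts of calls were set against other splits of the 6 libraries, and neither 10 splits nor the 4 that part all 3 pairs can give a share under 0.05. With the block the real split called 110 genes, as many as 1 of 4 splits, and the highest other called 0. Without it the real split called 0, as did 10 of 10. Lists called were 16 with the block, as many in 1 of 4 splits, with 14 in the highest other, which exchanged the labels of the H1 pair. Without it they were 11, as many in 3 of 10 splits, with 14 in the highest other, and of the splits with 14, 1 set batch 2 whole against batch 3 whole and the other exchanged the labels of the H1 pair.

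KO minus WT differences rose with exon length in each batch (Spearman's rho across genes 0.223, 0.190 and 0.207). For the 65 genes that fell, the correction left a ratio of 0.935 of the median change (95% bootstrap interval 0.911 to 1.06) and 58 calls, which argues against this trend as the whole cause. For the 45 that rose the ratio was 0.830 (0.770 to 0.949) and 19 calls were left, so a part from the trend stays open. A smaller astrocyte share in KO libraries, as the whole cause, needs the astrocyte list at or below the -0.73 median of the genes that fell, but its 26 members had a median of -0.248 (-0.46 to -0.02), and GFAP, AQP4, GJA1, ALDH1L1 and SLC1A3 pooled gave -0.19 (-0.39 to 0.002). The bootstrap intervals of this paragraph resample genes, and the pooled interval takes its genes as independent. Genes of the same libraries can move together, so these intervals do not measure the spread between libraries. A smaller shift in astrocyte RNA and an effect of genotype stay open, and how far the neurons themselves express these markers was not measured.

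UBE3A was higher, not lower, in the libraries labelled KO. Counts shared with overlapping genes are argued against, since 0.4% of its exon bases overlap another gene on the same strand. Removing the length and GC trend left a ratio of 0.734 of its log2 difference, 0.20 against 0.27, so the trend may account for part of it. For the H1 pair, whose labels conflict, the block called 0 genes and 14 lists with its 2 labels exchanged against 110 genes and 16 lists as labelled, and 4 splits are too few for a share under 0.05. As labelled, log2 differences of the H1 pair correlated positively across genes with those of batches 1 and 2 (Pearson's r = 0.099 and 0.107). After the length and GC correction r was 0.103 and 0.105. These signs go with the labels as given, but rest on 1 H1 pair. UBE3A counts alone do not show whether a label is wrong, whether the H1 labels run the same way as those of H9 is not settled, and no biological explanation was tested.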
